A study of Mus musculus with 40 samples.

How the data were processed

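Polyadenylated RNA from the medial prefrontal cortex of female mice was sequenced in 40 libraries, 5 in each of 8 groups given by age, drink and injection in the sample labels. Per the labels' protocols, RNA was extracted with a column kit and libraries were made with a rapid RNA-seq library kit. The antibiotics, the time of day of tissue collection and the strand setting of counting are not given in the sources used here. The authors deposited 1 table of raw read counts for 56980 genes, not normalized, whose column names end as the gene count files of the aligner STAR do. Per the submitters' processing notes, STAR 2.7.10a and DESeq2 were used with the mouse build mm10, and no role is given for DESeq2. The annotation used for counting is not given in the sources used here. The table holds 0 rows without a gene.

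Gene identifiers were matched without their version to the symbols of the reference annotation, which gave 52073 matches, or 91.4%. With the version only 35 identifiers matched, so the reference is not the annotation of the counts and no coordinates are printed. A symbol shared with another identifier was held by 135 identifiers. Without a stated strand, reads of antisense and overlapping genes cannot be told apart, and such genes are called uncertain where they are named. Totals per library, ranged from 8.64 to 12.1 M (M for mega), so that 3 counts in 1 library stood for 0.248 to 0.347 CPM. These floors cover counting error only. Replicate libraries were compared by the chi-square of their counts per gene, which lay between 2.2 and 16.15 for all pairs within a group, so none was treated as a duplicate. The female-specific transcript Xist was read at 441 to 865 CPM in all 40 libraries, and genes of the Y chromosome had at most 1 count.

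Counts were analysed with R 4.3.3 and edgeR 4.0.16. Genes were kept by filterByExpr over the 8 groups with a minimum count of 10 and a minimum total of 15, which left 17880 genes with 99.75% to 99.82% of the counts of each library. Library sizes were scaled by TMM, and robust quasi-likelihood models with 1 coefficient per group were fitted to all 40 libraries together, so that all groups shared 1 estimate of the spread. The biological coefficient of variation was 9.14%. Each of 14 comparisons was a contrast of these coefficients tested by the two-sided quasi-likelihood F test, and p-values were adjusted by Benjamini and Hochberg over all genes tested. Adjusted p-values in the text are from edgeR unless another tool is named. A gene is called at an adjusted p under 0.05. The SE of a log2 fold change was taken as its size divided by the square root of F. Means and SDs are of CPM over the 5 libraries of a group, while fold changes come from the model.

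The comparisons, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except for 2 added alternatives and the coding used for the replicate block. The tests of explanations for patterns in the data were chosen after the data had been seen. For the phase of the clock, a clock shift behind Rbm3 and Cirbp, and the 1351 genes called in adolescents without single libraries, they were chosen after the results they bear on had been seen. For a comparison with calls the rule took up to 8 higher and 8 lower called genes with the smallest p among genes with a mean of at least 1 CPM and an established symbol. To these it added up to 3 called members of each list and 6 genes given whatever their p where antibiotics or morphine was tested against its plain control (Oprm1, Penk, Fos, Fkbp5, Bdnf and Mbp). For a comparison without calls it took 2 higher and 2 lower genes with the smallest p. The text names a part of the genes this rule gave, chosen after the tests were seen and with preference for calls that held without single libraries. AC167245.1 is outside the rule and was chosen after its values were seen. Results of 1 gene that the rule gave are not reported here.

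Lists of cell type markers and pathways, of which 29 had at least 5 tested members, were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, with adjustment over the lists of a comparison. Members called over all genes tested are counted beside members that pass when adjusted over the list alone. The alternatives were size factors of the RLE type, no filter on low counts, a stricter filter of at least 1 CPM in 5 libraries, DESeq2 1.42.0, limma-voom with sample quality weights, a fit of only the compared groups, the replicate number as a block within age, surrogate variables from sva 3.50.0 (3 used), and leaving out each library in turn. DESeq2 was given all 56980 deposited genes, while limma-voom was given the 17880 that edgeR tested. Counts of DESeq2 therefore differ from those of edgeR in both tool and gene set. Added after the data were seen were an offset for GC content and gene length and covariates from 6 cell marker lists. The replicate block was planned, but the coding used for it replaced a first one after the counts under that one had been seen. For each comparison the libraries were regrouped at random 99 times in a fit of only these libraries. Correlations across libraries were tested with 1e+05 permutations, two-sided.

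The models were tested on simulated counts of 17880 genes. At each size 66 or 67 genes, drawn from the more highly expressed ones, were changed in 1 group. Counts were drawn independently for each gene and library, with no structure shared by samples. The shares and counts below therefore do not cover such a structure, or a comparison in which many more genes change. For antibiotics in adolescents given morphine, 29.9%, 73.1% and 98.5% of genes changed by 0.3, 0.5 and 1 on the log2 scale were recovered, with 4 unchanged genes called. For morphine in adults on water the shares were 38.8%, 73.1% and 95.5%, with 12 unchanged genes called, and for the interaction in adolescents 9%, 35.8% and 72.7%, with 1. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Reads were not analysed here.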

Results

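RNA from the medial prefrontal cortex of female C57BL/6J mice, a standard inbred laboratory strain, was measured in 40 libraries. Mice entered the experiment as adolescents, starting on postnatal day 25, or as adults, starting on postnatal day 55. At each age they drank plain water or received oral antibiotics, and were injected under the skin with saline or with morphine at 15 mg/kg for 5 days. This gave 8 groups of 5 libraries. At each age the comparisons of antibiotics in saline and of morphine on water share their water-saline libraries. Those of morphine on antibiotics and of antibiotics under morphine share their antibiotics-morphine libraries, and the interaction uses every group of that age. Results of such comparisons are not independent. The tissue label reads brain, and the prefrontal region is named in the title of the series. Nothing in the labels says that the libraries came from separate mice, so the p-values measure only the spread between these samples. Total counts per library ranged from 8.64 to 12.1 M (M for mega). Group means ranged from 9.28 ± 0.4 M (SD, n = 5) in adolescents on water and saline to 10.45 ± 1.14 M (SD, n = 5) in adolescents on water and morphine.

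The first principal component, with 9.56% of the variance of the 1000 most variable genes, had a mean of 6.37 ± 5.28 (SD, n = 5) in adolescents given antibiotics and morphine. The other adolescent groups lay at -3.59 ± 2.78 on water and saline, -7.38 ± 3.2 on antibiotics and saline and -7.01 ± 4.08 on water and morphine (SD, n = 5 each). Adults were at -2.03 ± 2.65 on water and saline, 3.43 ± 4.66 on antibiotics and saline, 2.98 ± 2.12 on water and morphine and 7.23 ± 5.61 on antibiotics and morphine (SD, n = 5 each). Of the adolescent antibiotics-morphine libraries, replicate 5 stood apart, at -1.59 on the first component and -7.35 on the second.

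**Figure D1:**
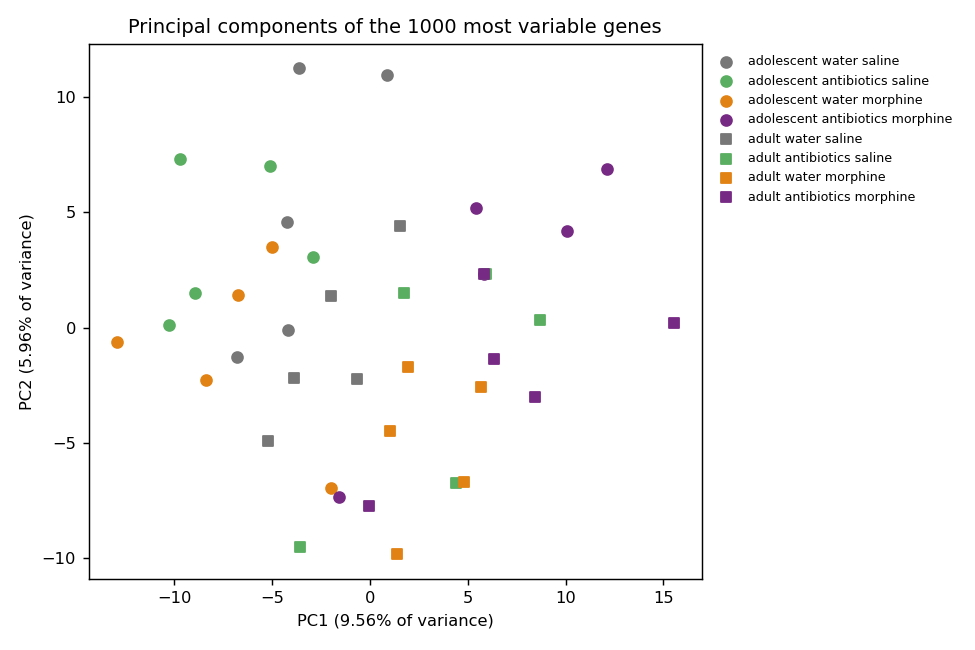
Each point is 1 of 40 libraries, placed by the first principal component (x axis, 9.56% of variance) and the second (y axis, 5.96% of variance), with circles for adolescents, squares for adults and colours for drink and injection. The adolescent antibiotics-morphine circles lie to the right of the other adolescent groups except for replicate 5 at -1.59.

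**Figure D2:**
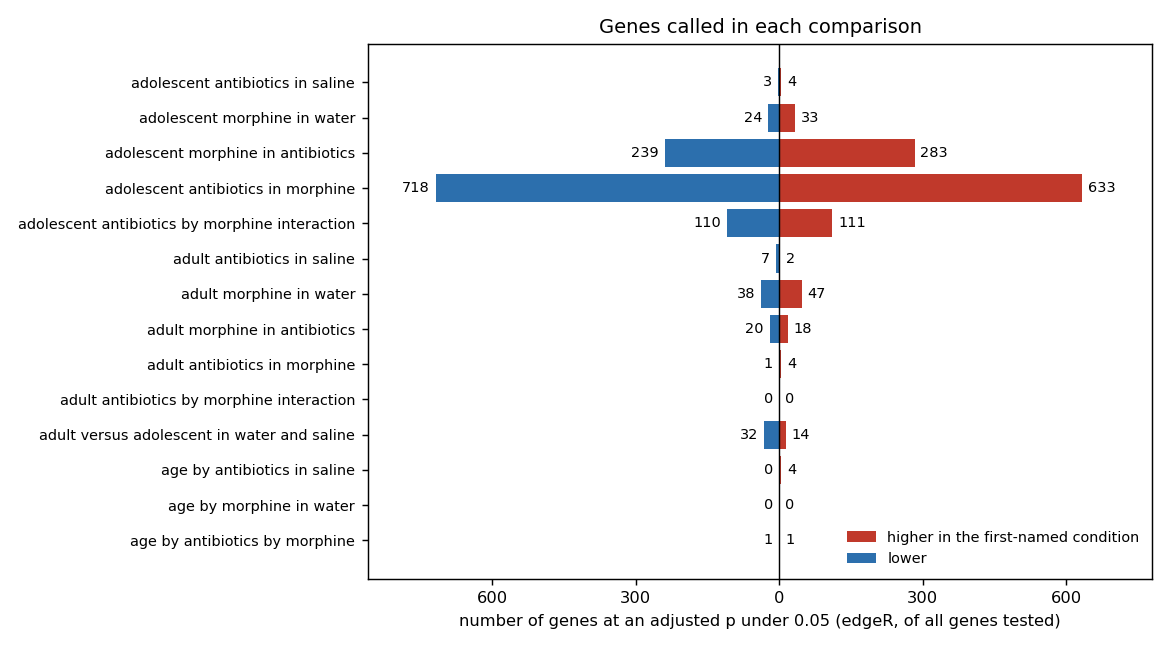
Bars give the number of genes at an adjusted p under 0.05 in each of 14 comparisons, to the right where higher in the first-named condition (or in adults for the comparisons with age) and to the left where lower. The longest bars, 633 and 718 genes, belong to antibiotics against water in adolescents given morphine.

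The effect of antibiotics without drug was read from saline-injected mice. In adolescents, Klf10, a transcription factor induced by TGF-beta, was 1.45-fold higher with antibiotics, at 53.4 ± 5.31 CPM against 36.9 ± 3.91 CPM (SD, n = 5 each; edgeR adjusted p = 0.00673). Btg2, an immediate early gene that restrains cell division, fell by 0.97 ± 0.18 (SE) on the log2 scale, from 37.8 ± 6.64 to 19.3 ± 3.31 CPM (SD, n = 5 each; edgeR adjusted p = 0.0265). Armcx5 was higher, with a log2 fold change of 0.52 ± 0.11 (SE), and the zinc finger genes Zfp950 and Zfp738 were lower, at -0.5 ± 0.1 and -0.39 ± 0.08. The receptor that binds morphine, Oprm1, had a log2 fold change of -0.09 ± 0.22 (SE; adjusted p = 0.929). The opioid peptide precursor Penk stood at -0.11 ± 0.15 (0.843) and the activity marker Fos at -0.6 ± 0.22 (0.354). The glucocorticoid receptor co-chaperone Fkbp5 was at 0.12 ± 0.12 (0.758), the neurotrophin gene Bdnf at 0.27 ± 0.1 (0.363) and the myelin gene Mbp at -0.26 ± 0.16 (0.618), where each bracket holds the edgeR adjusted p. In all, 7 of 17880 genes passed the test, 4 higher and 3 lower. Among 30 immediate early genes, 1 was lower over all genes tested and 7 passed when adjusted over the list alone. Astrocyte markers had negative fold changes in 15 of 16 members and all 13 oligodendrocyte precursor markers were negative. In each list 0 members were called over all genes and 4 adjusted over the list alone, where edgeR called 7 genes and counted 1744 at an unadjusted p under 0.05, while DESeq2 called 45 and limma-voom 17. Both lists were called by camera with its preset correlation (adjusted p = 4.86e-06 and 0.000118), but with an estimated correlation the adjusted p = 0.598 for astrocytes and adjusted p = 0.464 for precursors. Leaving out 1 library gave 13 calls without water-saline replicate 1, 12 without replicate 3 and 2 without replicate 5 of that group, and 2, 3, 2 and 0 without antibiotics-saline replicates 2, 3, 4 and 5. Klf10 lost its call without antibiotics-saline replicate 5 (adjusted p = 0.0673). Btg2 lost it without water-saline replicates 4 and 5 (0.0612 and 0.149) and antibiotics-saline replicates 2, 4 and 5 (0.103, 0.0799 and 0.0796). The other 3 named calls ended without any 1 antibiotics-saline library. Armcx5 also lost its call without water-saline replicates 4 and 5 and the zinc finger genes without replicates 2 and 5 of that group, with adjusted p-values up to 0.22 for Armcx5 and 0.155 for Zfp950 and Zfp738. In a fit of only the compared groups Armcx5, Zfp950 and Zfp738 lost their calls (edgeR adjusted p = 0.162, 0.083 and 0.153) at log2 fold changes of 0.51, -0.5 and -0.39. With surrogate variables both zinc finger genes did so (0.0692 and 0.0843) at -0.42 and -0.3.

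In adolescents on water, morphine raised the clock genes Dbp, Per2 and Tef and lowered Btg2, Ccn1, Dusp1, Ier2 and Gadd45g. Dbp, a clock-controlled transcription factor, rose 1.65-fold, from 81.1 ± 12.7 to 134 ± 11.6 CPM (SD, n = 5 each; edgeR adjusted p = 1.07e-06). The period gene Per2 rose 1.97-fold, with a log2 fold change of 0.98 ± 0.15 (SE; adjusted p = 0.000403), and Tef, a relative of Dbp, rose 1.24-fold, at 0.32 ± 0.05 (SE; adjusted p = 4.5e-05). Btg2 fell by 1.99 ± 0.19 (SE) on the log2 scale, from 37.8 ± 6.64 to 9.64 ± 2.43 CPM (SD, n = 5 each; adjusted p = 5.8e-08). The same water-saline libraries were the control for antibiotics, where Btg2 was lower too, so the 2 falls are not independent. The matricellular protein gene Ccn1 fell by 2.14 ± 0.25 (SE), the MAP kinase phosphatase gene Dusp1 by 1.18 ± 0.15, Ier2, an immediate early gene, by 1.11 ± 0.16 and the growth arrest gene Gadd45g by 0.99 ± 0.15. Each was lower in 5 of 5 libraries than any water-saline library, with edgeR adjusted p-values of 4.06e-07, 7.36e-06, 1.54e-05 and 4.6e-05. Of 18 tested circadian clock genes, 8 rose and 1 fell over all genes tested, and 13 passed when adjusted over the list alone (camera adjusted p = 6.71e-13; adjusted p = 2.87e-05 with an estimated correlation). Of 30 immediate early genes, 6 fell over all genes, and 19 passed adjusted over the list alone, 5 of them higher and 14 lower (camera adjusted p = 4.42e-07; adjusted p = 0.352 with an estimated correlation). Outside these lists, Ankrd33b, the sphingosine kinase gene Sphk2, the TGF-beta signal transducer Smad3 and the AMPK-related kinase gene Nuak1 rose 1.39-, 1.32-, 1.3- and 1.29-fold. Ovca2 and Mir212 fell by 1.4 ± 0.16 and 1.89 ± 0.34 (SE) on the log2 scale. Both are read as uncertain, because the labels do not say whether counting used strand and overlapping transcripts then cannot be told apart. Oprm1 had a log2 fold change of 0.15 ± 0.21 (SE; adjusted p = 0.782), Penk -0.26 ± 0.15 (0.442), Fkbp5 0.15 ± 0.12 (0.596), Bdnf 0.27 ± 0.1 (0.256) and Mbp -0.18 ± 0.16 (0.648). Fos, at -0.95 ± 0.22 (adjusted p = 0.0431), lost its call without any of 8 of the 10 libraries, all but water-saline replicate 2 and water-morphine replicate 5, with an adjusted p of up to 0.136, and also in a fit of only the compared groups, at -0.96 (adjusted p = 0.107), and with surrogate variables, at -0.84 (0.39). In all, 57 genes passed, 33 higher and 24 lower, and the count was 37 without water-saline replicate 5 and 33, 36 and 33 without water-morphine replicates 1, 2 and 5.

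**Figure D3:**
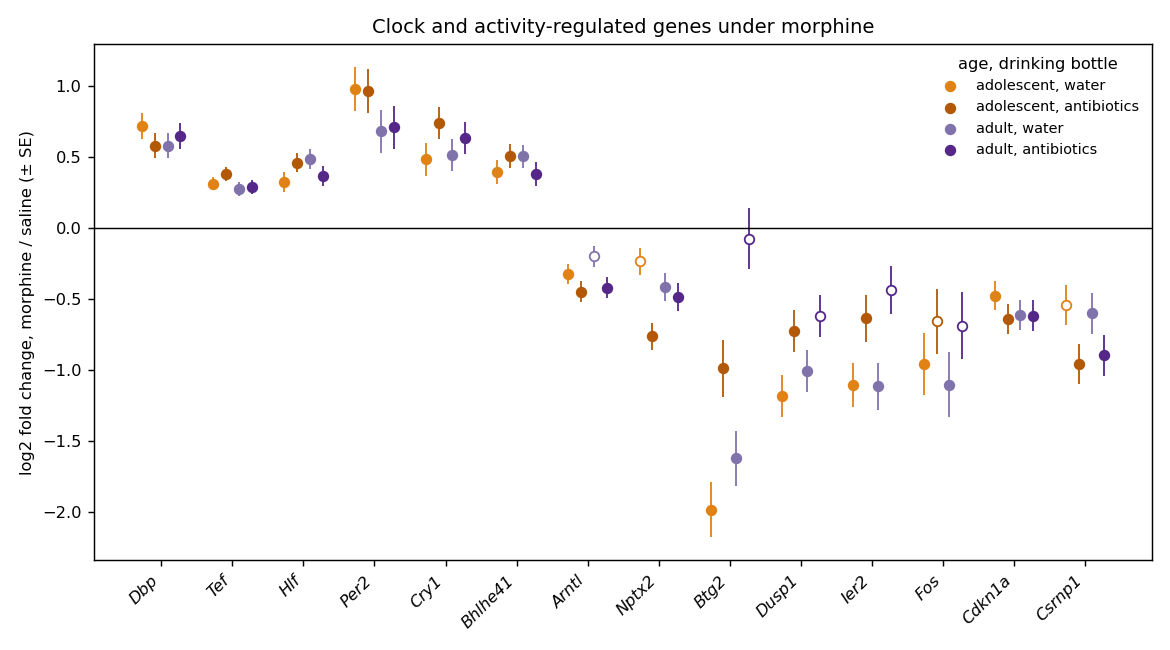
Points are log2 fold changes of morphine against saline (y axis) for 14 genes (x axis) in both ages and with both drinks, with bars of 1 SE, and open points mark an adjusted p of 0.05 or more. Dbp, Tef, Hlf, Per2, Cry1 and Bhlhe41 lie above 0 in all 4 comparisons, while Btg2 ranges from -1.99 in adolescents on water to -0.07 in adults on antibiotics.

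In adolescents on antibiotics, morphine raised Fkbp5 and the clock genes Cry1, Tef, Hlf and Dbp, and lowered Bdnf, Nptx2, the chaperones Calr and Hspa5 and the sterol genes Stard4, Hmgcs1 and Msmo1. Fkbp5 rose 1.7-fold, from 24.5 ± 2.42 to 41.7 ± 7.57 CPM (SD, n = 5 each; edgeR adjusted p = 3.83e-05). Bdnf fell by 0.66 ± 0.11 (SE) on the log2 scale, from 39.2 ± 1.73 to 24.8 ± 3.49 CPM (SD, n = 5 each; adjusted p = 0.000112). Nptx2, an activity-regulated pentraxin that acts at excitatory synapses, fell by 0.76 ± 0.1 (adjusted p = 5.29e-06). Cry1, a core clock repressor, rose 1.68-fold and the clock output genes Tef, Hlf and Dbp rose 1.3-, 1.38- and 1.5-fold, while the clock activator Arntl fell by 0.45 ± 0.07 (SE; adjusted p = 0.000112). Of 18 clock genes, 11 rose and 1 fell over all genes tested, and 13 passed adjusted over the list alone (camera adjusted p = 5.42e-13; adjusted p = 3.31e-05 with an estimated correlation). Of 30 immediate early genes, 12 fell and 17 passed adjusted over the list alone, all lower (adjusted p = 0.0149 with an estimated correlation). Of 22 heat shock and chaperone genes, 6 fell and 12 passed adjusted over the list alone (adjusted p = 0.0149 with an estimated correlation). The endoplasmic reticulum chaperones Calr and Hspa5 were at -0.35 ± 0.07 and -0.37 ± 0.07 (log2 fold change ± SE). Of 22 cholesterol synthesis genes, 7 fell and 13 passed adjusted over the list alone, 12 of them lower. Stard4, which carries sterols between membranes, stood at -0.59 ± 0.1 and the synthesis enzymes Hmgcs1 and Msmo1 at -0.46 ± 0.08 and -0.44 ± 0.08 (log2 fold change ± SE; list adjusted p = 0.0149 with an estimated correlation). Csrnp1, the pseudokinase gene Trib1, the fatty acid carrier Fabp7, the cell cycle inhibitor Cdkn1a, Klf10 and the GABA-A receptor subunit Gabra2 fell by 0.96, 0.71, 1.07, 0.64, 0.58 and 0.36 on the log2 scale, and Rere and Tub rose 1.32- and 1.34-fold. Of 20 oligodendrocyte and myelin markers 2 rose and 3 passed adjusted over the list alone, with 16 positive fold changes (camera adjusted p = 0.000134; adjusted p = 0.571 with an estimated correlation). Of 17 endothelial markers 3 fell and 5 passed adjusted over the list alone, 4 of them lower (camera adjusted p = 0.00592; adjusted p = 0.571 with an estimated correlation). Of 15 striatal neuron markers 2 rose and 3 passed adjusted over the list alone (camera adjusted p = 0.714). Of 18 mural and fibroblast markers 0 were called by edgeR, where 2912 genes had an unadjusted p under 0.05, DESeq2 called 690 genes and limma-voom 1204, while 2 passed adjusted over the list alone, with a median of -0.38 (camera adjusted p = 3.53e-05; adjusted p = 0.529 with an estimated correlation). Of 77 cytosolic ribosomal protein genes 1 fell, and of 72 nuclear-encoded respiratory chain genes 2, as many adjusted over the list alone, with medians of -0.1 and -0.12 (camera adjusted p = 1.57e-06 and 1.13e-07; adjusted p = 0.571 for both with an estimated correlation). In all, 522 genes passed, 283 higher and 239 lower. The count was 311 and 284 without antibiotics-saline replicates 3 and 4, and 214, 327 and 970 without antibiotics-morphine replicates 2, 3 and 5. It was 1204 with limma-voom and 339 with surrogate variables. With an offset for GC content and gene length, added after the data were seen, it was 546, of which 452 were among the 522, and with covariates from 6 cell marker lists, also added then, 391, of which 259 were among them.

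Antibiotics against water in morphine-treated adolescents gave 1351 called genes, 633 higher and 718 lower. The antibiotics-morphine libraries are the same as in the morphine comparison on antibiotics above. Changes seen in both, as for Fkbp5, Bdnf, the chaperones and the sterol genes, are therefore not independent. A level particular to this group and effects of the treatments are not separated for them. Rbm3 and Cirbp, RNA-binding proteins induced by mild cold, rose 1.55- and 1.65-fold, to 82.3 ± 7.17 CPM from 53.1 ± 3.33 and to 78.9 ± 17.4 CPM from 47.7 ± 1.57 (SD, n = 5 each; edgeR adjusted p = 4.28e-07 and 4.33e-06). In the antibiotics-morphine libraries Cirbp was lowest in replicate 5. Rbm3 is read as uncertain, because the transcript Rbm3os is antisense to it and the strand setting of counting is not given. Fkbp5 rose 1.67-fold, from 25 ± 2.62 to 41.7 ± 7.57 CPM (SD, n = 5 each; adjusted p = 1.8e-05). Calr fell by 0.51 ± 0.07 (SE) on the log2 scale, from 299 ± 12.3 to 210 ± 31.2 CPM (SD, n = 5 each; adjusted p = 1.39e-06), and the chaperones Pdia6 and Hspa5 fell by 0.5 ± 0.07 and 0.48 ± 0.07. Bdnf fell by 0.66 ± 0.11, from 39.1 ± 4.22 to 24.8 ± 3.49 CPM (SD, n = 5 each; adjusted p = 5.7e-05). Of 22 heat shock and chaperone genes, 14 fell and 16 passed adjusted over the list alone, all lower (camera adjusted p = 2.95e-15; adjusted p = 0.00416 with an estimated correlation). Of 22 cholesterol synthesis genes, 11 fell and 1 rose, and 14 passed adjusted over the list alone (adjusted p = 0.0265 with an estimated correlation). Msmo1, Stard4 and Hmgcs1 were at -0.51 ± 0.08, -0.61 ± 0.1 and -0.49 ± 0.08 (log2 fold change ± SE). Of 25 glucocorticoid-responsive genes, 7 rose and 8 passed adjusted over the list alone (camera adjusted p = 0.000127; adjusted p = 0.24 with an estimated correlation). Of 18 clock genes 3 rose, and 4 passed adjusted over the list alone, 3 of them higher (camera adjusted p = 0.114). The GABA-A subunits Gabra2 and Gabrb1 were at -0.5 ± 0.07 and -0.48 ± 0.11 and the metabotropic glutamate receptor Grm3 at -0.48 ± 0.1 (log2 fold change ± SE). Of 14 GABA receptor genes these 2 fell, and 4 passed adjusted over the list alone (camera adjusted p = 0.000353; adjusted p = 0.472 with an estimated correlation). Of 24 glutamate receptor genes 4 fell and 2 rose, and 7 passed adjusted over the list alone, 2 of them higher (camera adjusted p = 0.0971). The excitatory neuron transcription factor Neurod6, the beta-tubulin Tubb2b, the histone deacetylase Hdac9, the nuclear export receptor Xpo1 and Ubxn2b fell by 0.55, 0.53, 0.34, 0.49 and 0.68. The Wnt ligand gene Wnt10b rose 4.42-fold, from 1.79 ± 0.402 to 7.96 ± 3.59 CPM (SD, n = 5 each), Klhl40 rose 2-fold, the non-coding Mir9-3hg 1.61-fold and Ppp1r1b, which encodes the dopamine-regulated phosphoprotein DARPP-32, 1.41-fold. Of 20 oligodendrocyte and myelin markers 18 had positive fold changes with 2 called (camera adjusted p = 0.00606; adjusted p = 0.637 with an estimated correlation), and 3 of 20 microglia markers were lower (adjusted p = 0.637 with an estimated correlation). Of 16 astrocyte and 17 endothelial markers 2 and 1 were lower, as many adjusted over the list alone (camera adjusted p = 0.0695 and 0.0676). Of 15 striatal neuron markers Ppp1r1b and Pde10a rose, and the same 2 passed adjusted over the list alone (camera adjusted p = 0.346), with Pde10a at a log2 fold change of 0.3 and, with surrogate variables, at 0.26 and no longer called (edgeR adjusted p = 0.0569). Of 18 mural and fibroblast markers 0 were called by edgeR, over all genes or adjusted over the list alone (camera adjusted p = 0.0425; adjusted p = 0.641 with an estimated correlation), where 4119 genes had an unadjusted p under 0.05 and DESeq2 called 1518 genes and limma-voom 2595. The count fell to 896 without water-morphine replicate 2, to 634 and 729 without antibiotics-morphine replicates 2 and 3, and was 2263 without antibiotics-morphine replicate 5. It was 326 with surrogate variables, of which 225 were among the 1351, and 2595 with limma-voom.

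**Figure D4:**
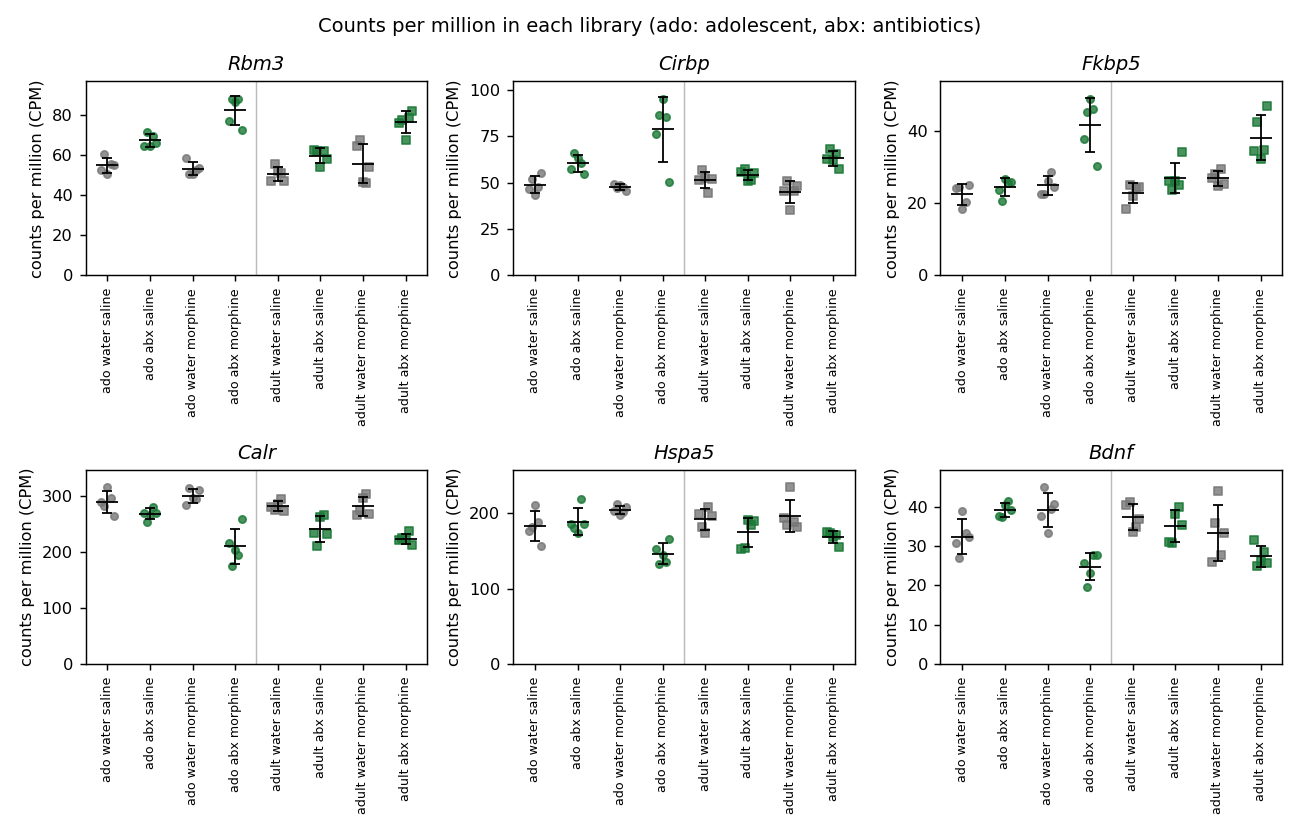
Each point is the CPM (y axis, from 0) of 1 library for Rbm3, Cirbp, Fkbp5, Calr, Hspa5 and Bdnf in the 8 groups (x axis, n = 5), green with antibiotics and grey without, and black bars give the mean and SD. In adolescents given antibiotics and morphine, Fkbp5 averaged 41.7 CPM and Bdnf 24.8 CPM.

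Whether morphine acted differently with antibiotics in adolescents was tested as an interaction, which called 221 genes, 111 with a more positive and 110 with a more negative morphine effect under antibiotics. Bdnf had the smallest p, with a log2 difference of -0.93 ± 0.15 (SE; edgeR adjusted p = 0.00166). Its morphine effect was 0.27 ± 0.1 on water and -0.66 ± 0.11 on antibiotics. Klf10, Rheb, a GTPase that activates mTORC1, the cyclophilin Ppid and Hspa5 had differences of -0.72 ± 0.13, -0.53 ± 0.1, -0.51 ± 0.1 and -0.53 ± 0.1 (SE), with adjusted p-values of 0.00878, 0.00878, 0.00904 and 0.0103. Fam214a, the CREB coactivator Crtc3, the transcriptional coregulator Rere and Arhgef10l had positive differences of 0.58 ± 0.11, 0.74 ± 0.14, 0.38 ± 0.08 and 0.53 ± 0.11. Of 22 heat shock and chaperone genes, 7 had a negative difference and 16 passed adjusted over the list alone (camera adjusted p = 1.39e-11; adjusted p = 0.02 with an estimated correlation). Of 22 cholesterol synthesis genes, 5 had a negative difference and 9 passed adjusted over the list alone (camera adjusted p = 9.49e-08; adjusted p = 0.0895 with an estimated correlation). Of 30 immediate early genes, 5 had a negative difference, and 8 passed adjusted over the list alone, 7 of them negative (adjusted p = 0.775 with an estimated correlation). Of 20 oligodendrocyte and myelin markers 18 had a positive difference, 5 passed adjusted over the list alone and 0 were called by edgeR over all genes, where 3027 genes had an unadjusted p under 0.05 and DESeq2 and limma-voom each called 457 (camera adjusted p = 2.61e-06; adjusted p = 0.562 with an estimated correlation). With surrogate variables as covariates, edgeR called 0 genes, Bdnf and the other 8 named among those lost, while DESeq2 and limma-voom each called 457 without them and 3027 genes had an unadjusted p under 0.05. The differences with these covariates were -0.68 for Bdnf, -0.7 for Klf10, -0.26 for Rheb, -0.43 for Ppid and -0.34 for Hspa5, and 0.36, 0.63, 0.21 and 0.33 for Fam214a, Crtc3, Rere and Arhgef10l. The count was 334 and 28 without water-saline replicates 3 and 5, 31 and 28 without antibiotics-saline replicates 3 and 4, 38 and 66 without water-morphine replicates 2 and 3, and 19, 48, 130 and 773 without antibiotics-morphine replicates 2, 3, 4 and 5.

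In saline-injected adults, Btg2 and Gadd45g were lower with antibiotics. The same water-saline libraries were the control for morphine on water, where both genes were lower as well. A level particular to this control group and effects of both treatments are not separated for these genes. Btg2 fell by 1.51 ± 0.19 (SE) on the log2 scale, from 29.5 ± 4.37 to 10.4 ± 1.87 CPM (SD, n = 5 each; edgeR adjusted p = 6.78e-05). Gadd45g fell by 0.91 ± 0.16, from 13.8 ± 2.27 to 7.38 ± 1.79 CPM (SD, n = 5 each; adjusted p = 0.00322), and both kept their calls without any 1 of the 10 libraries. Ccn1 was lower at -1.21 ± 0.24, together with the myosin light chain gene Myl6, Mex3b, the antiproliferative gene Tob1 and the G protein regulator Rgs2, at -0.38 ± 0.07, -0.43 ± 0.09, -0.41 ± 0.08 and -0.37 ± 0.08. Frmd6 was 1.32-fold higher. Leaving out 1 library ended these 6 calls in many cases. Ccn1 and Rgs2 lost theirs without any library but water-saline replicate 1 and antibiotics-saline replicate 4 (adjusted p up to 0.107 and 0.238), and Frmd6 without water-saline replicates 2 to 4 or antibiotics-saline replicates 1, 2, 3 or 5 (up to 0.192). The call ended without water-saline replicates 2, 3 or 5 or antibiotics-saline replicates 1, 3 or 5 for Myl6 (up to 0.132), and without these or antibiotics-saline replicate 2 for Tob1 (up to 0.0849). It ended without water-saline replicates 2 or 4 or antibiotics-saline replicates 1, 3 or 5 for Mex3b (up to 0.223). Mex3b and Rgs2 also lost their calls in a fit of only the compared groups (edgeR adjusted p = 0.0763 and 0.0849) at log2 fold changes of -0.44 and -0.37, and Rgs2 with surrogate variables (0.0593) at -0.33. Log2 fold changes of Oprm1, Penk, Fos, Fkbp5, Bdnf and Mbp were -0.25 ± 0.21, 0.09 ± 0.15, -0.51 ± 0.22, 0.24 ± 0.12, -0.1 ± 0.1 and 0.05 ± 0.16 (SE), with edgeR adjusted p-values of 0.74, 0.899, 0.421, 0.474, 0.814 and 0.954. Of 30 immediate early genes, 1 fell over all genes tested and 4 adjusted over the list alone (camera adjusted p = 1.65e-08; adjusted p = 0.217 with an estimated correlation). In all, 9 genes passed, 2 higher and 7 lower. The count was 16, 2, 4 and 4 without water-saline replicates 1 to 4, and 4, 4, 46 and 2 without antibiotics-saline replicates 1, 3, 4 and 5.

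In adults on water, morphine raised the clock genes Hlf, Dbp, Bhlhe41, Nr1d2 and Tef and lowered the immediate early genes Btg2, Ier2, Dusp1, Jun and Fosb. Hlf and Dbp rose 1.4- and 1.5-fold, from 200 ± 13.3 to 281 ± 18 CPM and from 94.5 ± 6.48 to 141 ± 17.7 CPM (SD, n = 5 each; edgeR adjusted p = 3.89e-05 and 0.000141). The clock repressors Bhlhe41 and Nr1d2 rose 1.42- and 1.32-fold and Tef 1.21-fold. Btg2 fell by 1.62 ± 0.2 (SE) on the log2 scale, from 29.5 ± 4.37 to 9.56 ± 3.27 CPM (SD, n = 5 each; adjusted p = 1.51e-05). Ccn1, Ier2, Gadd45g and Dusp1 fell by 1.85 ± 0.26, 1.12 ± 0.16, 1.03 ± 0.16 and 1.01 ± 0.15, and the AP-1 subunits Jun and Fosb and the cell cycle inhibitor Cdkn1a by 0.58 ± 0.1, 0.75 ± 0.14 and 0.61 ± 0.11. Of 18 clock genes, 9 rose over all genes tested and 14 passed adjusted over the list alone, 11 of them higher (camera adjusted p = 9.28e-13; adjusted p = 4.39e-05 with an estimated correlation). Of 30 immediate early genes, 14 fell and 18 passed adjusted over the list alone, all lower (camera adjusted p = 9.21e-32; adjusted p = 0.00196 with an estimated correlation). Sphk2, Ankrd33b and Tmem132d rose 1.33-, 1.34- and 1.38-fold. All 20 oligodendrocyte and myelin markers had positive fold changes, with 0 called by edgeR over all genes, where 85 genes were called and 1978 had an unadjusted p under 0.05, while DESeq2 called 146 genes and limma-voom 219. Of these markers, 9 passed adjusted over the list alone (camera adjusted p = 3.08e-11; adjusted p = 0.218 with an estimated correlation). Oprm1, Penk, Fkbp5, Bdnf and Mbp had log2 fold changes of -0.25 ± 0.21, 0.12 ± 0.15, 0.23 ± 0.12, -0.17 ± 0.1 and 0.45 ± 0.16 (SE), with adjusted p-values of 0.721, 0.837, 0.449, 0.586 and 0.251. Fos fell by 1.1 ± 0.23 (adjusted p = 0.0156), a call lost without water-saline replicate 5 (0.0635) and water-morphine replicate 3 (0.0619). In all, 85 genes passed, 47 higher and 38 lower. The count was 41, 46, 36 and 43 without water-saline replicates 2 to 5, and 30, 51, 153 and 50 without water-morphine replicates 1, 3, 4 and 5.

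In adults on antibiotics, morphine raised Dbp 1.57-fold, from 89.5 ± 8.46 to 140 ± 14.4 CPM (SD, n = 5 each; edgeR adjusted p = 6.92e-05). Cry1, Tef and Hlf rose 1.56-, 1.22- and 1.29-fold, and Arntl fell by 0.42 ± 0.07 (SE) on the log2 scale (adjusted p = 0.00125). Klf10 fell by 0.65 ± 0.1, from 51 ± 10.1 to 32.6 ± 3.05 CPM (SD, n = 5 each; adjusted p = 0.000125). Csrnp1, the kinase gene Stk40, Cdkn1a and the ERK phosphatase gene Dusp6 fell by 0.9 ± 0.14, 0.47 ± 0.08, 0.62 ± 0.11 and 0.51 ± 0.09. As in adolescents, Fkbp5 was called higher and Nptx2 lower. Over 10 fits that each left out 1 library, Fkbp5 lay at 0.41 to 0.59 and Nptx2 at -0.55 to -0.44. Fkbp5 lost its call in 6 of these fits (edgeR adjusted p up to 0.213) and Nptx2 in 2 (up to 0.0529). Fkbp5 also lost it with only the compared groups, at 0.5 (0.0822). Rbm3os, a transcript antisense to Rbm3, was higher at 0.59 ± 0.11 (adjusted p = 0.00175), and is read as uncertain because reads of the 2 strands cannot be told apart if counting did not use strand. Of 18 clock genes, 8 rose and 1 fell over all genes tested, and 12 passed adjusted over the list alone (camera adjusted p = 2.41e-07; adjusted p = 0.00275 with an estimated correlation). Of 30 immediate early genes, 6 fell and 15 passed adjusted over the list alone, all lower (camera adjusted p = 6.88e-22; adjusted p = 0.0157 with an estimated correlation). In all, 38 genes passed, 18 higher and 20 lower. The count was 15, 20 and 21 without antibiotics-saline replicates 2, 3 and 5, and 16, 17 and 21 without antibiotics-morphine replicates 2, 3 and 5. Whether the morphine effect on antibiotics differed with age was not tested by itself.

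Antibiotics against water in morphine-treated adults gave 5 called genes, 4 higher and 1 lower. Whether the antibiotics effect under morphine differed with age was not tested by itself. The larger count in adolescents therefore does not show such a difference. Rbm3 rose 1.37-fold, from 55.7 ± 9.88 to 76.2 ± 5.38 CPM (SD, n = 5 each; edgeR adjusted p = 0.00579), and Cirbp 1.4-fold, from 45.1 ± 5.78 to 63.3 ± 4.09 CPM (adjusted p = 0.0414). Etnppl, an enzyme of phosphoethanolamine breakdown found in astrocytes, rose 2.13-fold, and Rbm3os, uncertain like Rbm3 for the reason of strand, 1.44-fold. Calr fell by 0.34 ± 0.07 (SE) on the log2 scale (adjusted p = 0.031 for these 3). Of 22 heat shock and chaperone genes all 22 had negative fold changes, 1 was called and 8 passed adjusted over the list alone (camera adjusted p = 4.15e-10; adjusted p = 0.0394 with an estimated correlation). Rbm3 lost its call without water-morphine replicates 3 (adjusted p = 0.0822) and 4 (0.0825), and Cirbp without any 1 of the 10 libraries (up to 0.19). Etnppl lost it without any but antibiotics-morphine replicate 1 (up to 0.12), Calr without any but antibiotics-morphine replicate 4 (up to 0.13) and Rbm3os without any but water-morphine replicate 2 and antibiotics-morphine replicate 1 (up to 0.147). Rbm3, Rbm3os and Calr also lost their calls in a fit of only the compared groups (edgeR adjusted p = 0.138, 0.128 and 0.0709), with log2 fold changes of 0.46, 0.54 and -0.32 there. The count was 1, 2, 0, 0 and 1 without water-morphine replicates 1 to 5 and 3, 1, 1, 3 and 1 without antibiotics-morphine replicates 1 to 5, where edgeR counted 1434 genes at an unadjusted p under 0.05 with all libraries and DESeq2 called 21 and limma-voom 12.

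The interaction of antibiotics and morphine in adults called 0 genes with edgeR, with 1214 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom. The smallest p was that of Btg2, with a log2 difference of 1.55 ± 0.29 (SE; edgeR adjusted p = 0.104). Gadd45g, Arid3b and Rps6ka3 had differences of 0.98 ± 0.23, -1.04 ± 0.24 and -0.42 ± 0.1, each at an adjusted p of 0.391. Btg2 passed the test without water-morphine replicate 5 (adjusted p = 0.0114), which was the 1 gene called then.

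Adult controls differed from adolescent controls in 46 genes, 14 higher and 32 lower in adults. Gpr17 and Enpp6, which mark cells at the start of myelination, were lower in adults, at 43.4 ± 3.26 against 73.1 ± 15 CPM and at 1.99 ± 0.457 against 5.51 ± 1.43 CPM (SD, n = 5 each; edgeR adjusted p = 0.000386 and 0.00104). Bcas1 and the myelin gene Mal had log2 fold changes of -0.76 ± 0.14 and -0.7 ± 0.13 (SE). Marcksl1, a regulator of the actin cytoskeleton in growing neurites, fell by 0.67 ± 0.08 from 136 ± 5.38 to 85 ± 5.49 CPM (SD, n = 5 each; adjusted p = 7.55e-08). Ass1, an enzyme of arginine synthesis, was 1.68-fold higher in adults, at 31.2 ± 1.51 against 18.6 ± 2.1 CPM (SD, n = 5 each; adjusted p = 2.42e-06), and Jade2 and the heat shock factor Hsf4 were 1.29- and 1.57-fold higher. Clec2l, Lsm11 and Apc, a Wnt pathway regulator, were lower at -0.48 ± 0.08, -0.49 ± 0.09 and -0.46 ± 0.08 (log2 fold change ± SE). Of 13 oligodendrocyte precursor markers, 3 were lower and 8 passed adjusted over the list alone (camera adjusted p = 5.33e-13; adjusted p = 0.014 with an estimated correlation). Of 20 oligodendrocyte and myelin markers, 5 were lower and 11 passed adjusted over the list alone (camera adjusted p = 2.24e-16; adjusted p = 0.104 with an estimated correlation). Perineuronal net components had 0 of 15 members called over all genes by edgeR, where 1788 genes had an unadjusted p under 0.05, DESeq2 called 116 genes and limma-voom 61. Adjusted over the list alone 7 passed, all lower (adjusted p = 0.0401 with an estimated correlation). Clock genes were higher as a list, with 16 of 18 fold changes positive and 2 passing adjusted over the list alone (camera adjusted p = 4.14e-05; adjusted p = 0.0161 with an estimated correlation). The count was 26, 95, 24 and 29 without adolescent replicates 2 to 5, and 26, 22 and 27 without adult replicates 2, 4 and 5.

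Whether the antibiotics effect in saline differed with age was tested directly. The difference, adult minus adolescent, was 0.71 ± 0.14 for Csmd3, 0.53 ± 0.11 for the endocytosis gene Fcho2 and 0.46 ± 0.09 for Phc3, a Polycomb subunit (log2 ± SE; edgeR adjusted p = 0.0383, 0.0393 and 0.0393). Csmd3 averaged 36.7 ± 3.35 and 27.1 ± 2.63 CPM on water and antibiotics in adolescents and 33.1 ± 4.89 and 40 ± 5.02 CPM in adults (SD, n = 5 each). The fourth gene called, AC167245.1, was named after its values were seen, and its group means of 0.0853 to 0.839 CPM in these 4 groups lie near the level of 3 counts, which was 0.248 to 0.347 CPM per library, so no fold is given. All 3 lost their calls without adolescent water-saline replicate 2, antibiotics-saline replicates 1 or 2, adult water-saline replicate 3 or antibiotics-saline replicate 3, with edgeR adjusted p-values for Csmd3 of 0.057, 0.0666, 0.107, 0.058 and 0.085. Fcho2 also lost its call without adolescent water-saline replicate 5, antibiotics-saline replicate 4, adult water-saline replicates 2 or 5 or antibiotics-saline replicate 5 (up to 0.187). Phc3 lost it without adolescent water-saline replicates 1 or 5 or adult water-saline replicates 2 or 4 (up to 0.144). Csmd3, Fcho2 and Phc3 also lost their calls in a fit of only the compared groups (edgeR adjusted p = 0.062, 0.0782 and 0.0782) and with surrogate variables (0.0857, 0.0857 and 0.31). Their differences were 0.71, 0.53 and 0.45 in the first of these fits and 0.7, 0.54 and 0.36 in the second. The count was 0, 2, 0, 0, 2 and 8 without adolescent water-saline replicates 2 and 5 and antibiotics-saline replicates 1, 2, 4 and 5. It was 7, 1, 0, 7, 7, 0 and 11 without adult water-saline replicates 1 to 3 and antibiotics-saline replicates 1 to 4, where edgeR counted 1801 genes at an unadjusted p under 0.05 with all libraries and DESeq2 called 42 and limma-voom 6.

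The morphine effect on water differed with age in 0 genes by edgeR, with 1788 at an unadjusted p under 0.05, 48 called by DESeq2 and 0 by limma-voom. DESeq2 was run without the filter on low counts, and edgeR without that filter called 55. The potassium channel gene Kcng4 had a difference, adult minus adolescent, of 1.51 ± 0.34 and the acyl-CoA synthetase gene Acsl6 of 0.33 ± 0.08 (log2 ± SE; edgeR adjusted p = 0.191 and 0.201). The proton pump subunit gene Atp6v0c had a difference of -0.4 ± 0.09 (adjusted p = 0.175). Without adolescent water-saline replicate 1 the test called 8 genes, and without replicate 3 of that group 2 genes.

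The interaction of antibiotics and morphine itself differed with age in 2 genes, 1 with a positive and 1 with a negative difference. The negative one was AC167245.1, named after its values were seen, with group means of 0.0853 to 1 CPM over the 8 groups (edgeR adjusted p = 0.00366). These means lie near the level of 3 counts, so no fold is given. The count was 1 without any of 22 of the 40 libraries. In adolescents these were water-saline replicates 2, 4 and 5, antibiotics-saline replicates 1, 3 and 4, water-morphine replicates 2 to 4 and antibiotics-morphine replicates 2 and 4. In adults they were water-saline replicates 2 to 4, antibiotics-saline replicates 1, 2 and 5, water-morphine replicates 1 and 2 and antibiotics-morphine replicates 1, 3 and 4. The count was 9, 6, 8, 5, 6 and 7 without adolescent water-saline replicates 1 and 3, antibiotics-saline replicate 5, water-morphine replicate 1 and antibiotics-morphine replicates 1 and 5. It was 10, 4, 11 and 8 without adult antibiotics-saline replicate 4, water-morphine replicates 3 and 4 and antibiotics-morphine replicate 5.

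Fold changes of comparisons that share no library were correlated across the 17880 genes, which are not independent replicates, and 4 such pairs were computed. Spearman's rho of the morphine effects on water and on antibiotics was -0.078 in adolescents and 0.096 in adults. It was 0.074 between the morphine effects on water in both ages and -0.009 between the antibiotics effects in saline. Of 99 regroupings of the labels, 50, 40, 53 and 95 gave a rho as large in size, so none of the 4 values exceeded what regrouped labels gave.

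Over all comparisons, camera with its preset correlation called 148 combinations of a list and a comparison, and 16 of these held with an estimated correlation. They were the clock genes in the 4 morphine comparisons and between ages, the immediate early genes under morphine in adults with either drink and in adolescents on antibiotics. The heat shock and chaperone genes held in adolescents under morphine with antibiotics, under antibiotics with morphine and in their interaction, and in adults under antibiotics with morphine. The others were the cholesterol synthesis genes in adolescents under morphine with antibiotics and under antibiotics with morphine, and the oligodendrocyte precursor and perineuronal net lists between ages. The adolescent results for the chaperone and cholesterol lists all use the same antibiotics-morphine libraries, so they are not independent of each other.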

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

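In this part, the tests with the GC content and gene length offset and with the cell marker covariates use alternatives that were chosen after the data had been seen, and the sizes and calls of the 1351 genes without single libraries were examined after the counts had been seen. A library was picked out when its distance to the nearest of the other 4, divided by the range of its group, passed Dixon's 95% critical value. Chance alone does this in about 5% of groups, and here it happened in 17 of 316 combinations of a gene and a group and in 1 of 24 combinations of a library measure and a group.

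In adolescents given antibiotics and morphine, replicate 5 lay apart for Hlf at 291 CPM (others 245 to 258), Tub at 235 (290 to 303), Grm3 at 59.5 (44.3 to 47.7) and Ppid at 51.4 (37.7 to 41.2), and replicate 1 for Arntl at 24.2 (25.5 to 25.9). In adolescents on water and morphine, replicate 3 was low for Per2 at 44 CPM (64.7 to 72.5) and high for Msmo1 at 83.1 (63.9 to 66.8). Among saline-injected adolescents, Mir212 was at 2.68 CPM in water replicate 5 (2.98 to 3.05), Fabp7 at 9.49 in antibiotics replicate 2 (15.2 to 17.3) and Hspa5 at 219 in antibiotics replicate 4 (173 to 185). In adult controls, replicate 5 lay apart for Ccn1 at 12.5 CPM (9.28 to 10.1), Apc at 442 (477 to 486) and AC167245.1 at 0.542 (0.0966 to 0.109), and replicate 1 for Jun at 50.1 (62.2 to 64.5). In adults on antibiotics and saline, replicate 5 was high for Fkbp5 at 34.3 CPM (23.7 to 26.3), replicate 4 for Cdkn1a at 32.4 (23.7 to 25.5), and replicate 1 had a total of 10.2 M counts (M for mega) (9.2 to 9.49). Ankrd33b was at 145 CPM in adult water-morphine replicate 4 (173 to 180).

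The effects of 2 ages or of 2 drinks differed by their own test for the following. The antibiotics effect in saline was more positive in adults than in adolescents for Csmd3 by 0.71, Fcho2 by 0.53 and Phc3 by 0.46 on the log2 scale. For AC167245.1 it differed as well (edgeR adjusted p = 0.0383), as did the interaction of antibiotics and morphine between ages (adjusted p = 0.00366). No fold is given for it, because the gene lay near the level of 3 counts, at 0.0853 ± 0.089 CPM in adolescents on antibiotics and saline and 1 ± 0.513 CPM in adolescents on antibiotics and morphine (SD, n = 5 each). In adolescents, the morphine effect differed between drinks in 221 genes. This count was 19 without antibiotics-morphine replicate 2. With surrogate variables edgeR called 0, where DESeq2 and limma-voom each called 457 without them.

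Of the technical explanations weighed for the 1351 genes called for antibiotics in adolescents given morphine, a trend with GC content and gene length is argued against as the whole cause, since an offset for it left 1296 calls, 1053 of them shared, and a median size of the log2 change of 0.325 against 0.346 without it. With the means of 6 cell marker lists as covariates there were 2298 calls, 1156 of them shared, and the median size was 0.362. The lists were of oligodendrocytes, astrocytes, microglia, endothelium, mural cells and fibroblasts, and striatal neurons. These values argue against a makeup of those cells, as far as the markers read it, as the whole cause. None of the lists was of cortical neurons, so a difference in their makeup stays open. The count depended on 1 library, at 634 without antibiotics-morphine replicate 2, less than 0.5 of its value, and at 2263 without replicate 5 of that group, while 477 of the 1351 genes were called without any 1 of the 10 libraries, so that these calls do not rest on 1 library. For the other 874 this stays open, although all 1351 genes kept their direction without any 1 library, with a median change of 0.319 to 0.399 in that direction, since genes chosen for passing the test over all 10 libraries would keep most of their change for that reason. With surrogate variables as covariates 326 genes were called, 225 of them shared, also less than 0.5 of the count. A structure of the samples that these variables pick up therefore stays open, also for part of the 477. An effect of antibiotics under morphine, which the design names, may also explain the calls. It is not separated from such a structure, nor from the dependence on 1 library for the 874.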

How the results depend on the processing

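All alternatives were planned except for the offset for GC content and gene length and the cell marker covariates, which were added after seeing the data. The coding used for the replicate block was also chosen after seeing the data. Of 226 called combinations of a named gene and a comparison, 108 kept their call in all settings and 0 changed sign. Combinations chosen for a call would mostly keep their sign for that reason. In 98 the call was lost in at least 1 setting other than leaving out a library, most often with surrogate variables (78) and with only the compared groups (38), and in 89 it was lost without 1 library, while 8 combinations gained a call. Counts with RLE size factors and with the stricter filter stayed within 1.5 times of those reported. The cause of the other shifts was not tested.

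In the order antibiotics in saline, morphine on water, morphine on antibiotics, antibiotics under morphine and their interaction, leaving out 1 library gave 0 to 13, 33 to 63, 214 to 970, 634 to 2263 and 19 to 773 genes in adolescents. In adults it gave 2 to 46, 30 to 153, 15 to 32, 0 to 3 and 0 to 1. The counts were 22 to 95 for age, and for the differences between ages 0 to 11 for antibiotics, 0 to 8 for morphine and 1 to 11 for the interaction. Where such a count was 0, edgeR counted 1744 genes for antibiotics in saline in adolescents, 1434 for antibiotics in adults given morphine, 1214 for the interaction in adults, 1801 for the antibiotics effect and 1788 for the morphine effect between ages at an unadjusted p under 0.05 with all libraries.

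Shifts of over 1.5 times were as follows. DESeq2 was run without the filter on low counts, so its shifts mix tool and gene set. It called 45 genes for antibiotics in saline, 99 for morphine on water and 457 for the interaction in adolescents. In adults it called 51 for antibiotics in saline, 146 and 58 for morphine on water and on antibiotics, 21 for antibiotics under morphine and 1 for the interaction. It called 116 for age, and 42, 48 and 56 for the differences between ages in the antibiotics effect, the morphine effect and the interaction. Limma-voom called 17, 1204, 2595 and 457 for antibiotics in saline, morphine on antibiotics, antibiotics under morphine and the interaction in adolescents. It called 14, 219 and 12 for antibiotics in saline, morphine on water and antibiotics under morphine in adults, and 14 for the interaction between ages. Without a filter on low counts there were 70, 137 and 485 for antibiotics in saline, morphine on water and the interaction in adolescents. There were 78, 213, 61, 44 and 15 for the adult comparisons, 139 for age, and 49, 55 and 112 for the differences between ages. A fit of only the compared groups gave 4 and 20 for antibiotics in saline and morphine on water in adolescents. It gave 15, 148 and 3 for antibiotics in saline, morphine on water and antibiotics under morphine in adults, 19 for age, and 1 for both the antibiotics and the morphine effect between ages.

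With surrogate variables there were 14, 35, 339 and 326 for the adolescent comparisons, of which the last shared 225 genes with the count reported, and 0 for the interaction, where 3027 genes had an unadjusted p under 0.05 without them, DESeq2 called 457 and limma-voom 457. In adults there were 14, 165, 70 and 38 before the interaction, and 118 for age. There were 0 by edgeR for the antibiotics effect and the interaction between ages, where DESeq2 called 42 and 56 and limma-voom 6 and 14, with 1801 and 2030 genes at an unadjusted p under 0.05. For antibiotics in adolescents given morphine, the added cell marker covariates gave 2298.

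The replicate block was fitted although the numbers did not pair the samples. Libraries with the same number had a median correlation of 0.005 in adolescents and 0.018 in adults, 3 of 30 pairs were over 0.1 at each age, and 6 and 7 of 20 libraries correlated best with their own number. The block gave 11 and 33 genes for antibiotics in saline in adolescents and adults, 8 for antibiotics under morphine and 2 for the interaction in adults, and 10 and 12 for the antibiotics effect and the interaction between ages. Its first coding, with number 1 as the reference, gave 4 genes for age and was replaced after that count had been seen, because the comparison then rested on the libraries of number 1. The coding used instead gave 52, and all other counts were identical under both.

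Depth limits the level that can be read, since 3 counts stood for 0.248 to 0.347 CPM per library.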

Other observations

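The test on the phase of the clock and the test of a clock shift behind Rbm3 and Cirbp were chosen only after the results were seen. The tests of regrouped labels and of tissue temperature were set down before their results were seen.

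In the comparison of the morphine effect on water between ages, all 20 oligodendrocyte and myelin markers had a positive difference, adult minus adolescent, with a median of 0.55 on the log2 scale. With edgeR 0 of them were called over all genes, where 1788 genes had an unadjusted p under 0.05, DESeq2 called 48 genes and limma-voom 0, while 13 passed adjusted over the list alone (camera adjusted p = 7.75e-13; adjusted p = 0.39 with an estimated correlation). Of 20 genes of immature neurons and neurite growth, 6 fell in adolescents given morphine with antibiotics against water, among them the tubulins Tubb2b, Tubb3 and Tubb2a. Of the list 9 passed adjusted over the list alone (camera adjusted p = 0.000237; adjusted p = 0.24 with an estimated correlation). Tubb3 and Tubb2a lost their calls with surrogate variables (edgeR adjusted p = 0.151 and 0.294), at log2 fold changes of -0.15 and -0.2, and Tubb2a also without antibiotics-morphine replicate 2 (0.0544). Nuclear-encoded genes of the respiratory chain had a median difference of the antibiotics effect in saline between ages of -0.22. Of these 0 of 72 were called by edgeR, where 1801 genes had an unadjusted p under 0.05, DESeq2 called 42 genes and limma-voom 6, while 2 passed adjusted over the list alone (camera adjusted p = 1.24e-21; adjusted p = 0.365 with an estimated correlation).

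Clock genes were higher under morphine at both ages and with both drinks, and a difference in clock phase at tissue collection is a candidate explanation. Arntl, Npas2 and Clock peak opposite to Dbp, Tef, Hlf, Per2 and Per3, so a shift in phase would lower them, and their median log2 fold change was below 0 and that of the second set above 0 in 4 of 4 morphine comparisons, where the second sign only restates the rise. In the order adolescents on water, adolescents on antibiotics, adults on water and adults on antibiotics, the medians were -0.083, -0.143, -0.198 and -0.137 for the first and 0.327, 0.514, 0.487 and 0.461 for the second. Arntl was called lower in 3 of these comparisons and was at -0.2 in adults on water (edgeR adjusted p = 0.248), while edgeR called Npas2 and Clock in 0 of 4 and Clock lay above 0 on water, at 0.01 in adolescents and 0.07 in adults, so the test rests mainly on Arntl. The time of collection is not given in the sources used here, so a drug effect on the clock and a difference in collection time between groups both stay open.

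Rbm3, uncertain for the reason of strand, and Cirbp were higher and chaperones lower with antibiotics under morphine at both ages, which a lower tissue temperature could produce. Over the 40 libraries with group means removed, the mean of Rbm3 and Cirbp ran against the mean of the heat shock and chaperone list, the 1 relation computed, with a Pearson r of -0.616 (permutation p = 0.00066) and a Spearman rho of -0.49 (permutation p = 0.0038). Without the 2 libraries farthest from the median, adolescent antibiotics-morphine replicate 5 and adult water-morphine replicate 3, r was -0.445, and it was -0.797 within adolescents and -0.345 within adults. A structure shared by the samples could also relate such means. No other lists were set beside them, so the relation does not single out temperature. The clock shift seen with morphine on water is argued against as the cause in adolescents. There Rbm3 and Cirbp had log2 fold changes of -0.05 ± 0.08 and -0.04 ± 0.1 (SE). Their mean was -0.042, against a mean rise of 0.678 with antibiotics under morphine. In adults the mean was -0.026 against 0.468, but the 2 genes lay apart, Rbm3 at 0.14 ± 0.08 and Cirbp at -0.19 ± 0.1. The clock shift is therefore not argued against for Rbm3 in adults. The SE of each mean, 0.063, takes the 2 genes as independent. A clock difference between drinks under morphine is not excluded by these values, as 3 of 18 clock genes rose in that comparison in adolescents (camera adjusted p = 0.114). These were Nr1d1, Ciart and Bhlhe41, which lost their calls with surrogate variables (edgeR adjusted p = 0.109, 0.729 and 0.181), at 0.17, 0.13 and 0.23. Ciart and Bhlhe41 also lost theirs in 7 of 10 fits that each left out 1 library, and Nr1d1 in 1. Body temperature was not measured in the data used here. Such a clock difference, temperature, a structure of the samples and an effect of antibiotics under morphine by another route therefore stay open.

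Each count of called genes was set beside 99 random regroupings of the same libraries, in a fit of only those libraries. For morphine in adolescents on antibiotics (545 genes, highest other 524), 1 of 100 splits, the real one, called as many. The same held for antibiotics in adolescents given morphine (1602, highest other 1310) and for morphine in adults on water (148, highest other 49). Such shares argue against chance but do not exclude it, since they were not adjusted over the 14 comparisons. The share was also 1 of 100 for the interaction between ages (2, highest other 1), where 1 of the 2 genes lay near the level of 3 counts. That count was 1 without some single libraries. It was 0 by edgeR with surrogate variables, where DESeq2 called 56 and limma-voom 14 without them. The splits therefore decide little there. Between 2 and 4 of 100 splits, the real one included, called as many for antibiotics in saline in adolescents (4, highest other 28) and adults (15, highest other 82). The same holds for morphine in adolescents on water (20, highest other 120), the interaction in adolescents (160, highest other 510), morphine in adults on antibiotics (27, highest other 47), and antibiotics in adults given morphine (3, highest other 9). It holds as well for age (19, highest other 41). In each of these comparisons some other split called more genes than the real one. The shares were not adjusted over the 14 comparisons, so chance is not excluded for them. For the differences between ages of the antibiotics and of the morphine effect, the fit of only these libraries called 1 gene each (highest other 2 and 15), and 4 and 3 of 100 splits called as many. Neither gene is called with all libraries, where edgeR called 4 and 0 genes, with 1801 and 1788 at an unadjusted p under 0.05, DESeq2 called 42 and 48 and limma-voom 6 and 0, so these splits say nothing of the 4 genes reported. For the interaction in adults edgeR called 0 genes (highest other 2). Any split calls at least 0, so the share of 100 of 100 was fixed in advance and decides nothing there. DESeq2 called 1 gene there, limma-voom 0, and 1214 genes had an unadjusted p under 0.05. Splits that called several times the real count, as for the antibiotics effects in saline, morphine in adolescents on water, the interaction in adolescents, antibiotics in adults given morphine and the morphine effect between ages, point to a structure of the samples. Which structure was not tested, and regrouped labels of an interaction can take up the main effects of the groups themselves.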
